A study of Mus musculus with 6 samples.

How the data were processed

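Direct RNA sequencing was applied to 3 samples of 2H-11 and 3 of SVEC4-10. Per the labels, RNA was taken with Trizol and 1 ug of total RNA per library was prepared with the Oxford Nanopore direct RNA kit SQK-RNA002, and genome builds mm10 and GRCm38 were used. The aligner, the counting tool, the gene annotation, the use of strand and the filters are not given in the sources used here. The authors deposited one table per gene with raw read counts, and the same counts as CPM, each count divided by its library total and given per 1e6 counts. The deposited table also holds other columns by the authors, namely DESeq2 log2 fold changes and adjusted p-values for 16107 genes. Their sign was read from the CPM values and is positive where 2H-11 is higher. In total 13 broken lines that named no gene were left out, which left 34724 genes. Of these, 19 identifiers shared a symbol with another identifier and were kept apart. The authors' ONT identifiers have no coordinates in the table and cannot be placed.

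Total counts per library were between 3628400 and 16798666, and between 20039 and 24286 genes had a count. The limit that 0 counts allow was taken as 3 counts over the summed counts of a line, which is 0.196 CPM for 2H-11 and 0.121 CPM for SVEC4-10, and bounds and intervals (95%) cover counting error only. A fold against a line at 0 is printed as a bound from that limit, and with 1 to 3 counts a ratio of summed counts, each over its line's total, is printed with its exact counting interval. Coordinates and transcript lengths came from GENCODE M21 on GRCm38, in which 22022 of 22036 Ensembl identifiers were found and 99.7% of symbols were equal. Reads of close paralogs and processed copies could not be separated, and both lines share a strain that differs from the reference genome.

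The lines were compared on counts with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM, and the quasi-likelihood test had line as its only term. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the 13187 genes tested; fold changes are 2H-11 over SVEC4-10, and the biological coefficient of variation was 20.2%. The test was tested on simulated data with 50 genes changed at each fold. It recovered 2% of changes of 1.5-fold, 44% of 2-fold, 94% of 4-fold and 100% of 8-fold, with 7 false calls among 127. The data gave 4778 calls. With far fewer changed genes the adjusted threshold was stricter in the simulation, so these shares are not those of the real comparison.

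Before the data were examined, 23 gene lists were fixed, 17 on biology and 6 on other cell types and RNA quality. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The rule for named genes was also fixed then. It took the 6 genes with the largest increase and the 6 with the largest decrease among those past the threshold, with no overlap between the lines, at 50 CPM or more in the higher line and without a predicted-model symbol. It added 2 genes with the smallest p per biology list, or the most abundant where fewer passed, and the most abundant gene per other list. After the data were seen, 7 lists were added, on mesothelium, urothelium, interferon production and signalling, Hox genes, imprinted genes, Y-linked genes and contractile genes. The values of some single list members are not reported here.

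Alternatives were a block for replicate number, DESeq2 1.42.0, limma-voom, other size factors, library size alone, no filter, a filter of 20 counts in 3 libraries, robust dispersion, a test against a 2-fold change, leaving out mitochondrial and ribosomal protein genes, thinning to the smallest library, and leaving out each library. After seeing the data, 2 more were chosen, namely removal of a trend with transcript length and Ensembl genes only. All 10 splits of the 6 libraries into 3 and 3 were also fitted. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.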

Results

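Polyadenylated RNA of 2 mouse cell lines was read directly, without copying into cDNA, on a nanopore instrument. Both lines are SV40-transformed cells from the axillary lymph node of C3H/HeJ mice. The labels call 2H-11 tumor endothelial cells and SVEC4-10 normal endothelial cells, and the comparison of the 2 lines asks which transcripts differ between them. Each label belongs to a single line, so tumor or normal status cannot be told apart from any other difference between the lines. Each line was represented by 3 libraries. The total of counted reads was 5375133, 4105369 and 5825968 in 2H-11 replicates 1 to 3. It was 4278424, 3628400 and 16798666 in SVEC4-10 replicates 1 to 3, so the largest library was 4.63 times the smallest. The deposited table covered 34724 genes, of which 22036 carried Ensembl identifiers. The other 12688 carried identifiers given by the authors, written ONT and a number. By the authors' gene types, the table held 22036 known genes, 12214 new genes, 244 known long noncoding RNA genes and 230 new ones. The loci of the ONT identifiers are not given, so whether they lie outside annotated genes could not be checked. Levels below are read counts scaled by the total of their library, in the unit CPM, and each value after ± is the SD over the 3 libraries of a line (n = 3). Nothing in the labels says that the libraries of a line came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

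The lines differed in both directions, and the difference reached transcripts that were abundant in one line and uncounted in the other. Of 13187 genes tested, 2645 were higher in 2H-11 and 2133 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Together these 4778 genes made up 36.2% of those tested. A fold change of at least 2 was reached by 2075 of the higher genes and 1209 of the lower genes. In 46.8% of the genes tested, every library of one line lay above every library of the other, where chance gives 10%. Pearson correlations of log2 CPM across genes were 0.955 to 0.976 between libraries of 2H-11 and 0.967 to 0.975 between libraries of SVEC4-10. Between the lines they were 0.779 to 0.835. The ONT identifiers were called mostly in one direction, with 1326 higher and 226 lower in 2H-11. Among genes with Ensembl identifiers, 1319 were higher and 1907 lower, and a fit on Ensembl genes alone, chosen after seeing the data, gave 1657 higher and 1631 lower. Tested against a 2-fold change, 1134 genes were higher and 671 lower in 2H-11.

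The 6 genes most strongly higher in 2H-11 at 50 CPM or more had 0 to 4 counts in SVEC4-10. Myl9, a regulatory light chain of smooth muscle and non-muscle myosin (ENSMUSG00000067818, chromosome 2, 156775420 to 156781658 in GRCm38), stood at 277 ± 62.4 CPM in 2H-11 and had no count in SVEC4-10. It was at least 2281-fold higher (adjusted p = 3.41e-12), taking the limit that 0 counts allow as 3 counts over the SVEC4-10 libraries, or 0.121 CPM. Parvb, a focal adhesion protein that binds integrin-linked kinase (ENSMUSG00000022438, chromosome 15, 84232043 to 84315688), was at 70.5 ± 6.34 CPM and at least 580.4-fold higher. Tex19.1, best known from germ cells and placenta (ENSMUSG00000039329, chromosome 11, 121146143 to 121148319), was at 60.3 ± 6.46 CPM and at least 496-fold higher. It has a close paralog, Tex19.2, with which the authors' counting could share reads. Mfap2, a microfibril component (ENSMUSG00000060572, chromosome 4, 141010418 to 141015984), was at 54.1 ± 3.38 CPM and at least 445-fold higher. Col6a3, a chain of type VI collagen (ENSMUSG00000048126, chromosome 1, 90765923 to 90843971), was at 53.4 ± 5.50 CPM and at least 439.7-fold higher. Adjusted p for these 4 genes was between 3.59e-11 and 7.34e-11. The type VI collagen chains Col6a1 and Col6a2 went the other way and were lower in 2H-11. Plac8 (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245) had 4 counts in SVEC4-10 and was 593-fold higher in 2H-11, at 117 ± 13.3 against 0.282 ± 0.249 CPM (log2 fold change 9.21, SE 0.40, adjusted p = 6.72e-12). SVEC4-10 replicate 3 held 68% of that line's counts. Without it the bounds fell to 730.2-fold for Myl9, 185.7 for Parvb, 158.8 for Tex19.1, 142.6 for Mfap2 and 140.7 for Col6a3, and Plac8 had 3 counts left in SVEC4-10, a ratio of 311 (95% counting interval 106 to 1510). Without SVEC4-10 replicate 2, Plac8 had 2 counts left and the ratio was 1244 (343.9 to 10280). Both Plac8 ratios are of summed counts and are not on the scale of the fitted 593-fold.

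The 6 genes most strongly lower in 2H-11 included 2 uroplakins. Upk1b (ENSMUSG00000049436, chromosome 16, 38773184 to 38800328) was at 0.434 ± 0.228 CPM in 2H-11 and 1387 ± 87.4 CPM in SVEC4-10 (log2 fold change -11.61, SE 0.29, adjusted p = 6.36e-15). Upk3b (ENSMUSG00000042985, chromosome 5, 136038496 to 136046487) was at 0.644 ± 0.248 and 1402 ± 407 CPM (log2 fold change -11.11, SE 0.31, adjusted p = 1.57e-14). Uroplakins are membrane plaque proteins of the bladder lining, and Upk1b and Upk3b are also made by mesothelial cells. Aldh1a1, a retinaldehyde dehydrogenase (ENSMUSG00000053279, chromosome 19, 20492715 to 20643465), was at 1.35 ± 0.340 and 1279 ± 87.5 CPM (log2 fold change -10.00, SE 0.26, adjusted p = 6.36e-15). Gpm6a, a neuronal and mesothelial membrane glycoprotein (ENSMUSG00000031517, chromosome 8, 54954843 to 55060871), had no count in 2H-11 and stood at 206 ± 41.1 CPM in SVEC4-10. It was at least 1053-fold lower, with the limit at 3 counts over the 2H-11 libraries, or 0.196 CPM (adjusted p = 6.72e-12). Angptl7, a secreted angiopoietin-like protein (ENSMUSG00000028989, chromosome 4, 148495183 to 148500460), also had no count in 2H-11. At 196 ± 132 CPM it was at least 1000-fold lower (adjusted p = 1.16e-09), and its level in SVEC4-10 rested largely on replicate 1, with 348 CPM against 131 and 109 CPM in replicates 2 and 3. Without that library the bound was 613.8-fold. Smpd3, a neutral sphingomyelinase (ENSMUSG00000031906, chromosome 8, 106252548 to 106337988), had 1 count in 2H-11 and 5775 in SVEC4-10, a ratio of 3578 in CPM of the summed counts (95% counting interval 642 to 141300, adjusted p = 4.27e-12). Its single count was in 2H-11 replicate 3. Without that library the line was at 0 and the bound was 750.9-fold lower, and without 2H-11 replicate 1 the ratio was 2321 (416.5 to 91710). The bounds without 2H-11 replicate 1 or 3 were 683.4 and 652.4 for Gpm6a, and 649 and 619.6 for Angptl7.

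**Figure D1:**
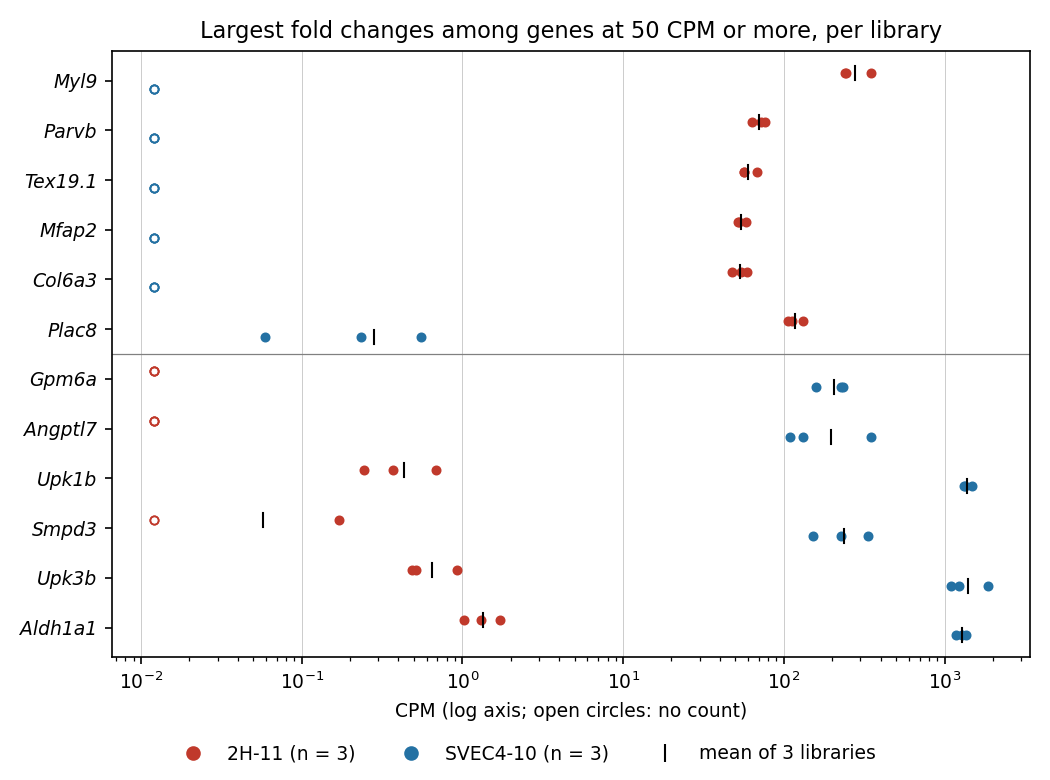
CPM of each library on a log axis for the 6 genes most strongly higher and the 6 most strongly lower in 2H-11 among those at 50 CPM or more in the higher line; filled circles are libraries, open circles are libraries with no count, drawn at the left edge, and vertical bars are the mean of the 3 libraries of a line. The libraries of the 2 lines do not overlap for any of the 12 genes, which the rule that chose them required.

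The lines were next compared over 23 gene lists fixed before the data were examined. From each list of biological processes the 2 members with the smallest p were to be named, and from each list of other cell types or RNA quality the most abundant member; all further members named here were chosen after their values were seen. Lists were tested against the other genes with camera at a preset correlation of 0.01, and p-values were adjusted over the 22 lists with enough members tested. Adjusted over the list alone, the numbers of members higher and lower equalled those over all genes tested for 17 lists, and for the other 6 they are given with the list. Setting members with no count in a line to their bound changed the median of 0 of the 23 lists. The median, the mean and the camera test did not share a sign for 6 lists, namely lymphatic endothelial, matrix proteases, leukocyte adhesion, cholesterol synthesis, ribosomal proteins and mitochondrially encoded genes. None of these 6 passed camera at an adjusted p under 0.05. Counts of 1 or 2 members in one direction changed by 1 or 2 when single libraries were left out for the lymphatic and tumor endothelial, p53, glycolysis, oxidative phosphorylation, cholesterol, unfolded protein, fibroblast and mural, ribosomal protein, and immediate-early and heat-shock lists.

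Most transcripts that define endothelial cells were at or near 0 in both lines. Of 21 pan-endothelial genes, 15 were under 1 CPM in all 6 libraries and 10 had no count in any library, among them Vwf, Tie1, Cldn5, Erg, Emcn and Icam2. Pecam1 had 1 count over the 3 libraries of 2H-11 and 0 over those of SVEC4-10, Cdh5 had 2 and 0, and Kdr had 3 and 8. Over a line, 0 counts allow a level of up to 0.196 CPM in 2H-11 and 0.121 CPM in SVEC4-10, for counting error only. Only 3 members had enough counts to be tested, and all 3 were higher in 2H-11. Ecscr, an endothelial surface protein, stood at 47.7 ± 6.33 CPM in 2H-11 against 1 count in SVEC4-10, a ratio of 1180 (95% counting interval 211 to 46670, adjusted p = 7.27e-11). Leaving out SVEC4-10 replicate 2, which held that count, gave a bound of 335-fold, and leaving out replicate 3 gave a ratio of 378 (67.6 to 14930). Egfl7, a secreted vessel protein, was 6.27-fold higher (log2 fold change 2.65, SE 0.42, adjusted p = 6.45e-05), at 5.40 ± 1.35 against 0.787 ± 0.0745 CPM. Eng, a TGF-beta co-receptor, was at 9.61 ± 2.60 against 2.46 ± 0.507 CPM (adjusted p = 0.000343). With so few members the list passed camera (adjusted p = 0.000267), and not with an estimated correlation (adjusted p = 0.222).

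Of 12 lymphatic endothelial genes, 6 were under 1 CPM in all 6 libraries, and Prox1, Lyve1, Ccl21a, Reln and Itga9 had no count in any library. Of 5 members tested, Thy1, a surface glycoprotein of stromal cells and T cells, was higher in 2H-11, at 39.6 ± 5.16 CPM against no count, which is at least 326-fold (104.2-fold without SVEC4-10 replicate 3; adjusted p = 2.43e-10). Mmrn1, a secreted multimerin of platelets and endothelium, was lower, at 6.34 ± 0.854 CPM in SVEC4-10 against no count in 2H-11, which is at least 32.4-fold (20.99 and 20.04 without 2H-11 replicate 1 or 3; adjusted p = 7.12e-07). Pdpn, a mucin-like protein of lymphatic endothelium and of many stromal cells, did not pass the threshold, at 195 ± 32.3 against 208 ± 2.36 CPM (adjusted p = 0.411). The list as a whole did not pass camera (adjusted p = 0.665).

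Genes reported in tumor vessels were more often higher in 2H-11. Of 13 tumor endothelial markers tested, 7 were higher and 2 lower, with a median log2 fold change of 2.50. Cd276, the immune checkpoint protein B7-H3, was 14.9-fold higher, at 46.8 ± 10.3 against 2.69 ± 1.37 CPM (adjusted p = 1.25e-08). Igfbp7, a secreted binding protein, was 9.48-fold higher, at 135 ± 11.9 against 12.5 ± 6.66 CPM (adjusted p = 4.94e-08). Cd248, endosialin, stood at 170 ± 50.6 against 20.1 ± 8.44 CPM (adjusted p = 1.42e-07). Plxdc2 and Bgn were the 2 lower members. Sparc, the most abundant member, was at 2571 ± 535 and 2433 ± 471 CPM and did not pass the threshold (adjusted p = 0.967). Esm1 had no count in any library, and Apln, Aplnr and Angpt2 were below 1 CPM on average in both lines. The list passed camera (adjusted p = 0.00117), and not with an estimated correlation (adjusted p = 0.126). Cd248, Mcam, Bgn and Sparc of this list are also made by pericytes and fibroblasts, and 7 of 11 fibroblast and mural genes tested were higher in 2H-11 as well.

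Ligands and receptors of vessel growth went both ways, with 7 of 14 tested members higher and 4 lower. Fgfr1 was 84.5-fold higher, at 19.0 ± 4.02 against 0.0992 ± 0.172 CPM (log2 fold change 6.40, SE 0.49, adjusted p = 9.06e-09); its 5 counts in SVEC4-10 were all in replicate 3, and without that library it was at least 50.1-fold higher. S1pr1, a sphingosine 1-phosphate receptor, had no count in SVEC4-10 and was at least 91.1-fold higher, at 11.1 ± 4.55 CPM (29.14-fold without SVEC4-10 replicate 3; adjusted p = 2.34e-07). The lower members were Fgf2, Pdgfb, Met and Efnb2. Vegfa was at 5.81 ± 1.05 and 6.44 ± 2.48 CPM and did not pass the threshold (adjusted p = 0.561). The list did not pass camera (adjusted p = 0.234).

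Matrix and mesenchymal genes went both ways. In the extracellular matrix list 8 of 20 tested members were higher and 7 lower in 2H-11; adjusted over the list alone, 8 were higher and 8 lower. Thbs2, an anti-angiogenic thrombospondin, had no count in SVEC4-10 and was at least 368-fold higher, at 44.7 ± 6.28 CPM (117.8-fold without SVEC4-10 replicate 3; adjusted p = 1.52e-10). Nid1, the basement membrane linker nidogen, was 36.3-fold higher, at 89.2 ± 10.1 against 2.06 ± 0.853 CPM (adjusted p = 6.93e-11). Its relative Nid2 was lower, at 6.21 ± 2.11 against 36.8 ± 18.9 CPM (adjusted p = 3.59e-06), as were the basement membrane chains Col4a1, Col4a2, Lama5 and Lamc1. The remaining lower members were chains of type VI collagen. Col6a1 was at 27.06 ± 0.2504 against 85.21 ± 36.35 CPM (adjusted p = 1.83e-05). Col6a2 was at 6.321 ± 1.426 against 28.1 ± 10.35 CPM (adjusted p = 6.72e-06). The list did not pass camera (adjusted p = 0.214), but did so on Ensembl genes alone (adjusted p = 0.0433; range over the alternatives 0.0433 to 0.682), and with an estimated correlation it passed under none of them (adjusted p 0.499 to 0.934). Of 16 mesenchymal transition genes, 5 were higher and 4 lower, and the list did not pass camera (adjusted p = 0.665). The higher members were the transcription factors Snai1, Snai2 and Twist2 together with S100a4 and Tgfbi. Tgfbi had no count in SVEC4-10 and was at least 114-fold higher, at 13.9 ± 2.35 CPM (36.51-fold without SVEC4-10 replicate 3; adjusted p = 1.74e-08). Without 2H-11 replicate 2 or SVEC4-10 replicate 3 only 2 members were lower. Tgfb3 was 7.21-fold lower in 2H-11, at 6.46 ± 2.30 against 44.3 ± 15.8 CPM (adjusted p = 3.29e-07). Vim was at 1383 ± 144 and 1193 ± 230 CPM and did not pass the threshold (adjusted p = 0.673).

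Among matrix proteases and their inhibitors, 6 of 19 tested members were higher and 5 lower, and the list did not pass camera (adjusted p = 0.868). Mmp2, gelatinase A, was 42.6-fold higher in 2H-11, at 34.6 ± 3.11 against 0.778 ± 0.573 CPM (adjusted p = 7.77e-10). Timp3, a matrix-bound metalloproteinase inhibitor, was 8.41-fold lower, at 451 ± 96.4 against 3541 ± 532 CPM (adjusted p = 3.5e-10). The other lower members were Mmp10, Mmp13, Plaur and Ctsl.

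Interferon-stimulated genes were lower in 2H-11 without exception among those tested. All 21 tested members were lower, with a median log2 fold change of -4.33. The summed level of all 22 members was 688 ± 59.4 CPM in 2H-11 against 5663 ± 317 CPM in SVEC4-10. Usp18, a negative regulator of interferon signalling, was 280.4-fold lower, at 1.02 ± 0.386 against 263 ± 64.9 CPM (log2 fold change -8.13, SE 0.32, adjusted p = 3.38e-12). Isg15, a ubiquitin-like modifier, was 20.1-fold lower, at 63.7 ± 5.36 against 1202 ± 53.5 CPM (log2 fold change -4.33, SE 0.18, adjusted p = 3.41e-12). The members included the transcription factors Irf7 and Irf9 and the virus sensors Ifih1 and Dhx58. Oas1a and Ifit3 have near-identical neighbours with which the authors' counting could share reads. The list passed camera (adjusted p = 2.04e-64) and also with an estimated correlation (adjusted p = 0.00891). Over the alternatives the latter ran from 0.00217 to 0.0711. It was lost with the block for replicate number (0.062), without 2H-11 replicate 1 (0.0711) and without 2H-11 replicate 3 (0.0540). All tested members were lower in each of these fits.

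Genes of class I antigen presentation moved the same way, with 10 of 14 tested members lower in 2H-11 and 0 higher. Psme1, a subunit of the interferon-inducible proteasome activator, was 3.95-fold lower, at 79.0 ± 2.40 against 292 ± 8.11 CPM (adjusted p = 2.58e-08). H2-K1, a class I heavy chain, was 4.01-fold lower, at 190 ± 35.0 against 715 ± 74.0 CPM (adjusted p = 2.86e-08), and B2m, its light chain, was at 854 ± 58.0 against 2571 ± 146 CPM (adjusted p = 6.9e-08). H2-K1 and H2-D1 are similar in sequence and vary between strains, so their counts are uncertain. Tap2, Psmb8, Irf1 and Calr did not pass the threshold. The median log2 fold change was -1.60. The list passed camera (adjusted p = 6.97e-07), and not with an estimated correlation (adjusted p = 0.0568).

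Adhesion molecules and chemokines were split, with 6 of 13 tested members higher and 5 lower; adjusted over the list alone, 6 were higher and 6 lower. Cxcl10, a chemokine that interferon induces, was 25.3-fold lower in 2H-11, at 7.19 ± 1.22 against 169 ± 23.2 CPM (adjusted p = 3.59e-11). Cxcl12, which attracts cells through Cxcr4, was 24.9-fold lower, at 5.01 ± 1.31 against 117 ± 4.25 CPM (adjusted p = 5.3e-11). The other lower members were Vcam1, Ccl2 and Ccl5. The higher members included Cxcl1, Cxcl5 and Cxcl16. The adhesion molecules Icam1, Sele and Selp did not pass the count filter and were not tested. The list did not pass camera (adjusted p = 0.474).

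**Figure D2:**
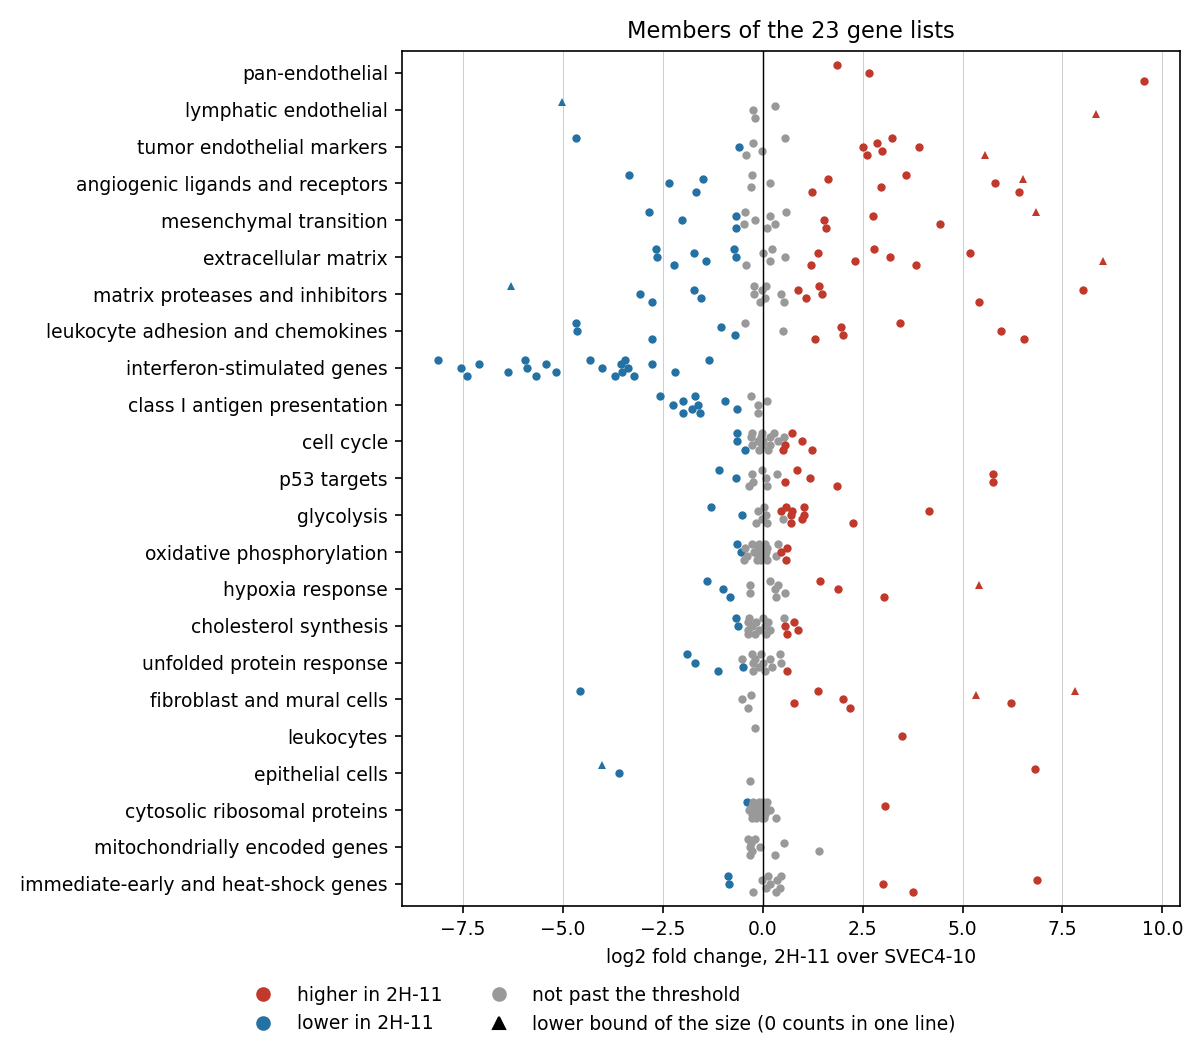
Fitted log2 fold change of 2H-11 over SVEC4-10, on a linear axis, for every tested member of the 23 gene lists; colours mark members higher, lower or not past an adjusted p of 0.05 in edgeR's quasi-likelihood test, and triangles mark members with no count in one line at the lower bound of their size. All 21 tested interferon-stimulated genes lie left of 0, while cell cycle, oxidative phosphorylation and ribosomal protein genes lie around it.

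**Figure D3:**
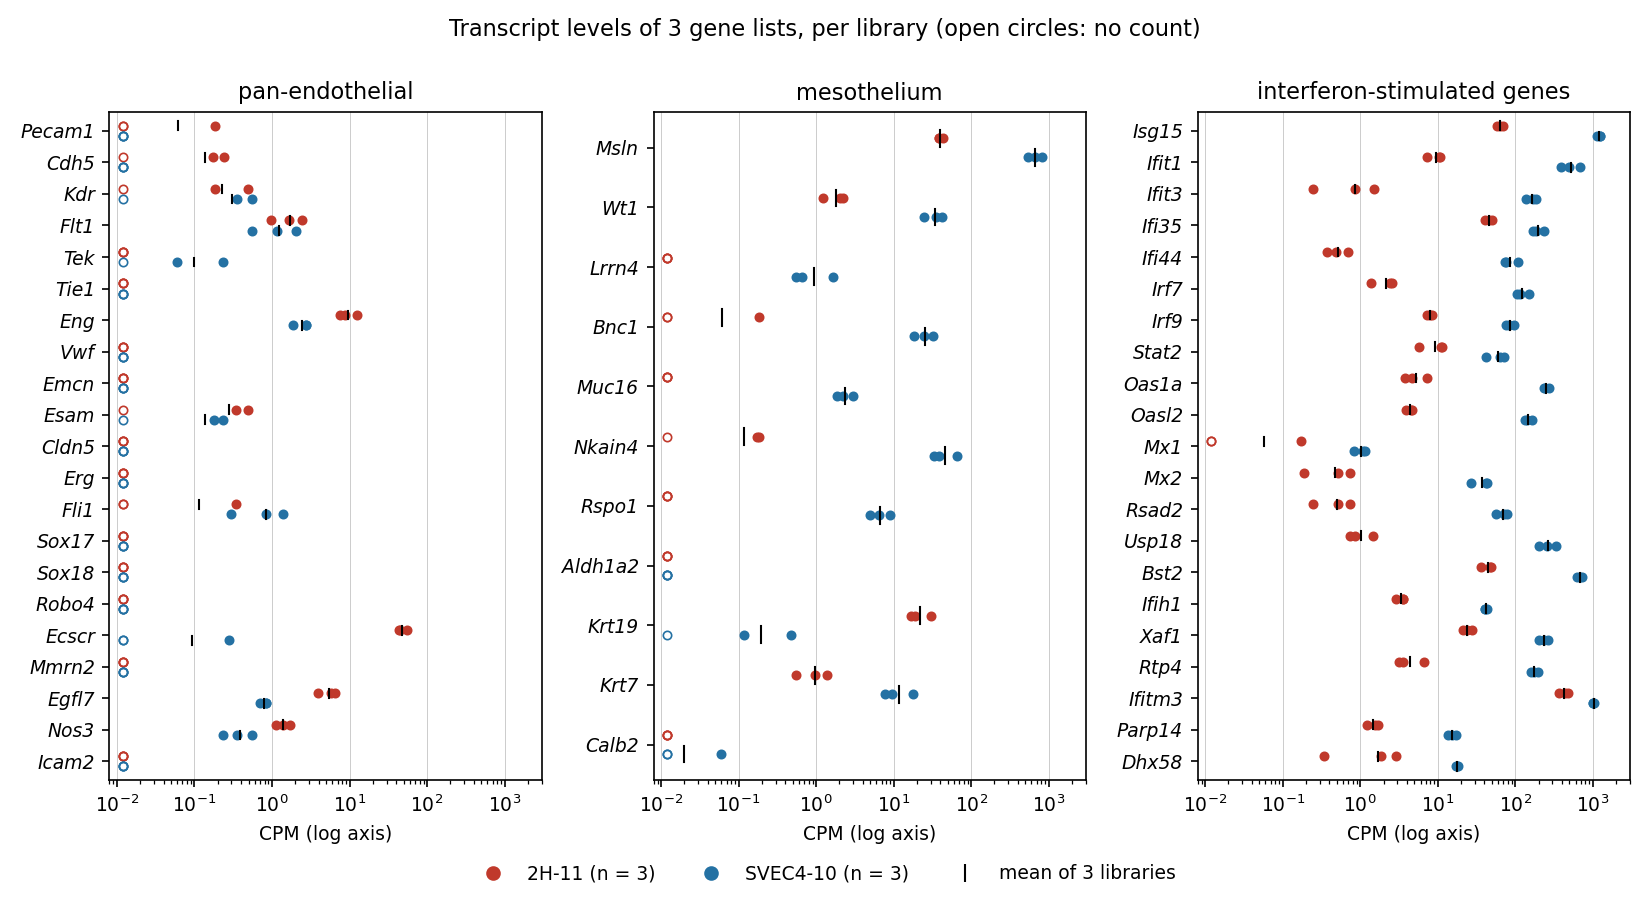
CPM of each library on a log axis for members of the pan-endothelial, mesothelium and interferon-stimulated gene lists, the mesothelium list having been written after the data were seen; filled circles are libraries, open circles at the left edge are libraries with no count, and vertical bars are means of 3 libraries. Of the 21 pan-endothelial genes 10 have no count in any library, while each interferon-stimulated gene drawn is lower in the 3 libraries of 2H-11 than in those of SVEC4-10.

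Glycolytic enzymes and transporters tended to be higher in 2H-11, with 10 of 19 members higher and 2 lower and a median log2 fold change of 0.50. Slc16a3, the lactate exporter MCT4, was 18.0-fold higher, at 56.1 ± 7.69 against 2.97 ± 0.292 CPM (log2 fold change 4.17, SE 0.26, adjusted p = 5.17e-10). Pkm, pyruvate kinase of muscle and proliferating cells, was 2.04-fold higher, at 4507 ± 259 against 2075 ± 158 CPM (log2 fold change 1.03, SE 0.15, adjusted p = 2.15e-05). Eno1 and Ldha were also higher, with log2 fold changes of 1.04 and 0.98. The lower members were Pfkfb3 and Tpi1. Only 6 members were higher without 2H-11 replicate 1, and 5 without SVEC4-10 replicate 3. No shift of the whole list passed camera (adjusted p = 0.0611); over the alternatives its adjusted p ran from 0.00537 to 0.204, and it passed under 7 of 16, among them library size alone (0.0383), Ensembl genes only (0.00537) and without 2H-11 replicate 3 (0.0403). With an estimated correlation its adjusted p was 0.245, and 0.138 to 0.619 over these 16, so it passed under none of them. Gapdh, which has many processed copies in the genome, was counted at 105 ± 15.5 and 107 ± 17.4 CPM, far below the other abundant enzymes of the list, so its counts may not cover its transcripts.

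Oxidative phosphorylation and cell cycle genes mostly did not pass the threshold. Of 24 oxidative phosphorylation genes, 3 were higher (Sdhb, Cox6c and Atp5a1) and 2 lower; adjusted over the list alone, 2 were higher and 2 lower. Ndufv1, of complex I, was 1.57-fold lower in 2H-11, at 213 ± 10.5 against 312 ± 40.3 CPM (adjusted p = 0.00461). Atp5b, of the ATP synthase, was 1.47-fold lower, at 1348 ± 60.5 against 1851 ± 118 CPM (adjusted p = 0.00603). Camera did not call the list (adjusted p = 0.803), and its counts changed to 4 lower without 2H-11 replicate 1 and to 1 higher without SVEC4-10 replicate 3. Of 23 cell cycle genes, 5 were higher (Plk1, Ccne1, Ccnd1, Birc5 and Cdc20) and 3 lower (Top2a, Cdk1 and Mcm7), and the list did not pass camera (adjusted p = 0.868). Ccnd1, cyclin D1, was 1.98-fold higher, at 75.3 ± 10.6 against 35.7 ± 0.617 CPM (adjusted p = 0.00051). Birc5, survivin, was 1.65-fold higher, at 383 ± 23.8 against 217 ± 24.3 CPM (adjusted p = 0.00188). Leaving out 2H-11 replicate 1 or 2, or SVEC4-10 replicate 2 or 3, left 3 cell cycle members higher.

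Among 15 tested targets of p53, 6 were higher in 2H-11, and Sesn1 and Fas were lower. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 3.62-fold higher, at 130 ± 13.4 against 33.8 ± 9.59 CPM (log2 fold change 1.86, SE 0.21, adjusted p = 1.12e-06). Pmaip1, the cell death protein Noxa, had 53 counts in 2H-11 and 1 in SVEC4-10, a ratio of 85.5 (95% counting interval 14.7 to 3442, adjusted p = 5.02e-06). Without SVEC4-10 replicate 1, which held that count, it was a bound of 23.88-fold, and without replicate 3 the ratio was 27.4 (4.71 to 1102). As a whole the list did not pass camera (adjusted p = 0.387).

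Hypoxia-response genes went both ways, with Bnip3, P4ha2, Ddit4 and Selenbp1 higher and Bnip3l, P4ha1 and Ero1l lower among 14 tested. Bnip3, a mitophagy receptor, was 8.25-fold higher, at 37.9 ± 5.42 against 4.44 ± 0.666 CPM (adjusted p = 2.97e-08). Selenbp1 had no count in SVEC4-10 and was at least 42.9-fold higher, at 5.21 ± 0.697 CPM (13.73-fold without SVEC4-10 replicate 3; adjusted p = 6.98e-07). Against the other genes, the list did not pass camera (adjusted p = 0.391). Of 20 cholesterol synthesis genes, 4 were higher and 2 lower, and the list did not pass camera (adjusted p = 0.97). Fdps was 1.48-fold higher, at 559 ± 64.7 against 355 ± 34.9 CPM (adjusted p = 0.00889), and lost its call without SVEC4-10 replicate 3 (adjusted p = 0.0846). Dhcr7 was 1.85-fold higher, at 17.8 ± 2.94 against 9.02 ± 2.93 CPM (adjusted p = 0.0131), and lost its call without 2H-11 replicate 2 and without SVEC4-10 replicate 2 or 3 (adjusted p = 0.0553, 0.0664 and 0.0637). The count of higher cholesterol genes was 2 without 2H-11 replicate 2 or SVEC4-10 replicate 1 and 1 without SVEC4-10 replicate 2 or 3, and that of lower ones was 4 without SVEC4-10 replicate 1, 1 without 2H-11 replicate 2 or SVEC4-10 replicate 2 or 3, and 0 without 2H-11 replicate 3. Of 18 unfolded protein response genes, Xbp1 was higher, and Hsp90b1, Ddit3, Dnajb9 and Trib3 were lower; adjusted over the list alone, 0 were higher and 4 lower. Ddit3, the stress transcription factor CHOP, was 3.71-fold lower, at 42.4 ± 2.49 against 147 ± 16.9 CPM (adjusted p = 1.85e-07). Dnajb9 was 3.26-fold lower, at 4.65 ± 1.23 against 14.2 ± 1.69 CPM (adjusted p = 0.000121). The set did not pass camera (adjusted p = 0.379).

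Part of the fibroblast and mural cell list was present in both lines. A mean of at least 1 CPM in both was reached by 7 of 15 members. Under 1 CPM in all 6 libraries were 4 members, and 2 of these had no count. The summed level of the list was 2445 ± 341 CPM in 2H-11 and 2617 ± 153 CPM in SVEC4-10. Acta2, smooth muscle actin and the most abundant member, was at 872 ± 238 and 1150 ± 298 CPM; it did not pass the threshold (adjusted p = 0.0716), but passed as lower in 2H-11 without 2H-11 replicate 1 (adjusted p = 0.00845) or SVEC4-10 replicate 1 (adjusted p = 0.00229). Of 11 members tested, 7 were higher in 2H-11 and Dcn, decorin, was lower; adjusted over the list alone, 7 were higher and 2 lower, and without SVEC4-10 replicate 1 the count of lower members was 3. Pdgfrb, a receptor of pericytes and fibroblasts, stood at 27.5 ± 5.04 CPM in 2H-11 with no count in SVEC4-10. Dcn was at 13.8 ± 2.59 against 307 ± 52.4 CPM. No shift of the whole list passed camera (adjusted p = 0.214).

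Leukocyte transcripts were at the floor, with 11 of 15 members under 1 CPM in all 6 libraries and a summed level of 10.3 ± 1.91 CPM in 2H-11 and 6.08 ± 3.33 CPM in SVEC4-10. Cd68 was at 3.46 ± 0.607 and 3.87 ± 0.958 CPM (adjusted p = 0.73). Only Cd68 and Coro1a were tested, too few for camera, and Coro1a was higher in 2H-11. Of 12 epithelial genes, Epcam, Cdh1 and Esrp1 had no count. Among 4 tested, Krt19, a keratin of simple epithelia, was 113-fold higher in 2H-11, at 22.0 ± 7.08 against 0.196 ± 0.243 CPM (log2 fold change 6.82, SE 0.50, adjusted p = 4.93e-09), while Krt7 and Krt8 were lower. Without SVEC4-10 replicate 1 or 3, Krt19 had 2 counts left in that line, with ratios of 226 (62.1 to 1875) and 87.6 (24.1 to 725.9). Both are ratios of summed counts and are not on the scale of the fitted 113-fold. The epithelial list did not pass camera (adjusted p = 0.803).

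Markers of RNA and library quality mostly did not separate the lines. Of 24 cytosolic ribosomal protein genes, Rpl3 was higher and Rpl10 lower in 2H-11; adjusted over the list alone, 1 was higher and 0 lower, and the list did not pass camera (adjusted p = 0.987). Rpl3 stood apart at 1168 ± 100.3 against 132 ± 18.5 CPM (log2 fold change 3.05, SE 0.17, adjusted p = 1.87e-10). Rplp1 was at 5651 ± 917 and 4242 ± 51.0 CPM and did not pass the threshold (adjusted p = 0.127), but passed without 2H-11 replicate 1 (adjusted p = 0.046) and with library sizes alone (adjusted p = 0.0182). Ribosomal protein genes have many processed copies, with which reads could be shared. Of 10 mitochondrially encoded genes tested, 0 passed the threshold in edgeR, and 1 did so when 2H-11 replicate 1 or 3 or any single SVEC4-10 replicate was left out. The gene mt-Nd6 was at 12260 ± 1226 and 9256 ± 1499 CPM (adjusted p = 0.154, and 0.0227 with library sizes alone). mt-Nd6 is a short gene on the strand opposite to most mitochondrial genes and mt-Co2 was near 0, at 0.763 ± 0.322 and 1.41 ± 0.996 CPM, so mitochondrial levels depend on how the authors' counting assigned reads. The mitochondrial list did not pass camera (adjusted p = 0.813). Of 14 immediate-early and heat-shock genes tested, Fosl1, Hspa1a and Hspa1b were higher and Atf3 and Hsp90aa1 lower, and the list did not pass camera (adjusted p = 0.369). Without SVEC4-10 replicate 1 the count of higher members was 5. Hspa1a and Hspa1b are near-identical copies, so their counts are uncertain. Hspa8 was at 1565 ± 267 and 1471 ± 163 CPM and did not pass the threshold (log2 fold change -0.01, adjusted p = 0.962), and its sign changed with the scaling.

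The authors' deposited table also held fold changes and adjusted p-values for 16107 genes, whose sign is positive where 2H-11 is higher. An adjusted p under 0.05 in the authors' deposited table was held by 5114 genes, 2785 of them higher in 2H-11 and 2329 lower. Of these, 4487 were among the genes tested here, and 4385 passed the present test in the same direction as in the authors' deposited table, with 0 in the opposite direction. With an adjusted p under 0.01 and a fold change of at least 2, the authors' deposited table held 3049 genes, of which 2652 were tested here and all 2652 passed in the same direction. Across the 13187 genes with both values, log2 fold changes here and in the authors' deposited table had a Pearson correlation of 0.987, where genes are not independent and both values come from the same counts.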

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

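The alternatives removal of a trend with transcript length and Ensembl genes only were chosen after seeing the data; the others were fixed before. Over 19 alternatives the number of genes called was between 3966 (at least 20 counts in 3 libraries) and 6971 (no count filter), except for 1805 in the test against a 2-fold change and 3288 on Ensembl genes only. Leaving out 1 library gave 4134 to 5149. The 2-fold test called 1134 genes higher and 671 lower, and in the deposited comparison against the present test 1797 of the authors' calls passed, because it asks for larger changes. Ensembl genes only, which leaves out the ONT identifiers, called 1657 genes higher, with 2764 of the deposited calls. The replicate block gave 4461 genes (2491 higher, 1970 lower). The interferon-stimulated list then had an adjusted p of 0.062 in camera with an estimated correlation. Deviations of equally numbered libraries correlated at -0.018, 0.051 and -0.003, so no shared deviation was seen. That does not show that the libraries are unpaired, and the labels do not say. Camera with an estimated correlation called 1 list and fry 13, against 4 with the preset one. Fry, and not camera, called the lymphatic endothelial, vessel growth, mesenchymal transition, extracellular matrix and p53 lists. The same held for the glycolysis, hypoxia, fibroblast and mural, and immediate-early and heat-shock lists. Fry gave all of these as higher in 2H-11, with adjusted p from 0.000731 (glycolysis) to 0.0421 (extracellular matrix). Fry tests a list against no change and camera tests it against the other genes, so their numbers answer different questions. The trend removal moved the median log2 fold change of all genes to 0.102, and library size alone to 0.099, from 0.003. The balance of directions moved too, with 2983 genes higher and 1820 lower after trend removal. Library size alone gave 2947 higher and 1747 lower.

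Of 52 named genes, 41 had the same direction and side of the threshold under every one of the 19 alternatives that gave them a value. No value came from the filter of 20 counts for Cd68, Egfl7 and Pmaip1, from thinning for Pmaip1, or from leaving out mitochondrial and ribosomal protein genes for Rplp1 and mt-Nd6. Hspa8 reversed with library size alone (0.094), at least 20 counts (0.006), thinning (0.008), trend removal (0.094) and Ensembl genes only (0.084), and lay between -0.137 and 0.091 when 1 library was left out; the cause was not tested. Counts of list members moved by more than 1.5 times in 116 of the tallies and stayed within that in 752. The planned pseudocounts and filters for normalized values were not run, since the table holds counts. In simulated data with the depth, spread and number of these libraries, 2% of 1.5-fold changes were recovered. Far fewer genes were changed there and the adjusted threshold was stricter, so that share is not that of the data. Whether depth, spread or number of libraries limits small changes was not tested.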

Other observations

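Apart from the splits of the libraries, all tests of explanations in this part and the 7 added lists were chosen after the results were seen, while the other lists were fixed before. Camera p-values of the added lists were adjusted over the added lists alone, apart from the 22 fixed lists. Hox transcripts differed in both directions, with 6 of 14 tested genes higher in 2H-11 (Hoxa9, Hoxb9, Hoxb13, Hoxc8, Hoxc9 and Hoxc10) and 3 lower (Hoxa7, Hoxc13 and Hoxd8). Hoxc8 stood at 12.3 ± 2.73 CPM in 2H-11 and 0.393 ± 0.380 CPM in SVEC4-10, while Hoxd8 had 2 counts in 2H-11 against 9.36 ± 0.235 CPM, a ratio of 72.5 (95% counting interval 19.8 to 602). The list did not pass camera (adjusted p = 0.176). Among 7 imprinted genes tested, Igf2r, Ndn, Snrpn and Grb10 were higher in 2H-11. Peg3 was lower, with 1 count in 2H-11 against 28.2 ± 4.90 CPM, a ratio of 443 (79.3 to 17520). Without 2H-11 replicate 3, which held that count, Peg3 was at least 89.2-fold lower, and without 2H-11 replicate 1 the ratio was 287 (51.4 to 11370). The imprinted list did not pass camera (adjusted p = 0.444). Y-linked transcripts were counted in both lines, with Ddx3y at 23.3 ± 8.58 and 45.5 ± 12.2 CPM and 1 of 4 tested genes lower in 2H-11 (2 adjusted over the list alone; camera adjusted p = 0.206).

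Of 12 contractile genes tested, Myl9 and Cnn1 were higher in 2H-11 and Cnn2 and Smtn lower (camera adjusted p = 0.156; adjusted over the list alone, 2 higher and 3 lower). The median, the mean and the test of this list did not share a sign. Cnn1 stood at 42.8 ± 6.34 against 0.255 ± 0.237 CPM. Of 12 genes of interferon production and signalling, Jak1 and Tmem173 were higher and Irf3, Tbk1, Ddx58 and Ifih1 lower (camera adjusted p = 0.156); Ifih1 is also in the interferon-stimulated list. Called ONT identifiers had 1326 higher and 226 lower in 2H-11, with median log2 fold changes over those tested of 0.77, against -0.10 for Ensembl genes.

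Most pan-endothelial transcripts were near 0 in both lines. A counting loss that takes annotated genes at large to near 0 is argued against by 7 lists of genes that every cell uses, where 1 of 141 members, or 0.709%, was under 1 CPM in all 6 libraries (upper limit 3.89%). Partial losses and the loss of single genes stay open, since Gapdh was counted at only 105.6 CPM and mt-Atp8 had no count. A limit of 1 CPM does not see a partial loss from an abundant gene. In addition, 9 ONT identifiers lay above 1000 CPM on average and summed to 27320 CPM. Without their loci it cannot be told whether they hold reads of annotated genes. Too few reads are argued against as well, since 16 of 21 members had an upper counting limit under 1 CPM in both lines. An origin of both lines from fibroblasts or mural cells stays open: 7 of 15 such members reached 1 CPM in both lines, and since transformed endothelial cells may take on these transcripts, the origins cannot be told apart.

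Mesothelial transcripts were higher in SVEC4-10, with 6 of 7 tested members lower in 2H-11 and Krt19 higher (camera adjusted p = 2.7e-09; 0.208 with an estimated correlation). Under 1 CPM in all 6 libraries were 2 of the 11 members, and 1 of these had no count. The summed level of all 11 members was 65.1 ± 6.59 CPM in 2H-11 and 801 ± 169.5 CPM in SVEC4-10, led by Msln at 40.0 ± 2.70 and 674 ± 132.5 CPM. Keratin-expressing mesothelial cells mixed into the cultures are argued against, since Krt8, Krt18 and Krt19 together reached 4.31 ± 1.33 CPM, or 0.64% of Msln, and 2.37% with Krt7 added. That holds only if the counting did not lose reads of these keratins, and a loss of single genes stays open. Urothelial cells are argued against too, since 10 other urothelial genes summed to 1.91 ± 1.75 CPM in SVEC4-10 (3.04 ± 1.65 in 2H-11), or 0.138% of Upk1b, and 0 of the 10 had enough counts to be tested. Keratin-poor mesothelial cells and expression by the SVEC4-10 cells themselves were not tested and stay open.

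Interferon-stimulated genes were lower in 2H-11. A trend with transcript length is argued against, since the median log2 fold change was -4.33 with the trend removed. Leukocytes mixed into the SVEC4-10 cultures are argued against by the low level of their transcripts. Of 15 leukocyte genes, 11 were under 1 CPM in all 6 libraries, and the sum in SVEC4-10 was 6.08 ± 3.33 CPM. That sum was 0.588 times the sum in 2H-11, but so near the floor the ratio rests on few genes and carries little weight. Transcription of an interferon gene in SVEC4-10 may contribute: Ifnb1 had 6 counts there and 0 in 2H-11 (exact binomial test, two-sided, p = 0.0889), and with so few counts it cannot be told apart from counting noise. A difference between the lines in interferon response stays open as well, and was not tested.

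For the number of genes called, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 4778 genes, and the highest of the other splits called 0. Each other split mixes the lines within its groups, which adds the line difference to the spread. Few calls there are therefore built in, and no conclusion is drawn from them.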
